A study of Mus musculus with 6 samples.

How the data were processed

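Total RNA of 6 samples of mouse primary hippocampal cells was measured, 3 infected with AAV1/2 carrying a Diras2 knockdown construct and 3 with a scrambled control. Per the labels' protocols, the RNA was amplified with a whole-transcript kit and the single-stranded DNA was biotin-labelled for Affymetrix arrays. The deposited values are log2 expression levels per probe set, made with RMA in Affymetrix Expression Console 1.2.1.20, per the submitters' processing notes. RMA corrects the background of each array, puts all arrays on one distribution and summarises the probes of a probe set, so a change shared by most genes would be hidden and weak signals are pulled towards a floor. A fold with 1 group at a low level, near the 4.73 of genes that did not pass, can therefore be understated, and whether such a group lay above background was not tested. The sequence of the knockdown construct, detection calls and probe-level intensities were not used here, so background correction and normalisation could not be repeated. The values have 2 decimals and run from 1.47 to 14.09. The number of arrays limits the precision.

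The table holds 41345 probe sets. A platform annotation pairs 23521 of them with 1 gene symbol and 1814 with several, and 16010 have no gene named here. The genes tested were the 22180 with a probe set of their own, and of 1082 genes with several probe sets the brightest over all arrays was used. Of the genes, 21994 were matched by Entrez number to a RefSeq gene table of assembly GRCm38.p6, 0 with a differing symbol, and 186 kept the name of the annotation. The table served for names and the genomic span of genes, and no coordinates are printed because the build behind the array annotation is not given in the sources used here.

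Samples were grouped by the treatment in their labels. The comparison was knockdown minus control with limma 3.58.1 (lmFit and eBayes without trend, R 4.3.3) and Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. A fold is 2 to the power of the difference between the group means. Diras2 also had an exact two-sided permutation test. For 20 pathway lists and 11 cell type marker lists, members called were counted over all genes and with adjustment over the list alone. Lists with 5 or more measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists tested, with an estimated correlation and fry as alternatives. Of these lists 1, which did not shift, is not reported here. Genes named in the text were Diras2, Diras1, the 12 called genes with the largest increase and the 12 with the largest decrease whose groups did not overlap, and the 4 members of each list with the smallest p. Intervals of list medians are bootstrap 95% intervals from 2000 draws of list members. They measure the spread between genes and not between samples, and take genes as independent. Figures were drawn with matplotlib 3.10.9.

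Groups share replicate numbers in the labels. Deviations from the group means, across genes, correlated at 0.43, 0.12 and 0.37 for the 3 same-numbered pairs and at -0.38 to 0.06 for the other pairs. All 3 were above the bound of 0.1 set in advance, so the numbers were taken to pair the samples, a pairing that comes from the data and not from the labels. The fit without a block remained the main one, and values with the replicate block stand beside the results it changes.

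The alternatives were the replicate block, leaving out each array, quantile normalisation or median centring, filters on dim genes, an intensity trend, robust fitting, array weights, RNA integrity as a covariate, all probe sets or the mean of a gene's probe sets, and other thresholds. The procedure was tested on simulated data for this comparison over 22180 genes with 200 changed. It called 11.3% of genes changed by 0.5 on the log2 scale, 71.8% of those changed by 1 and 97.0% of those changed by 2. All 123 called changed genes had the right direction, 5 unchanged genes were called, and 0 were called when nothing was changed. In this simulation changes of 0.5 were thus mostly missed. It drew genes independently and changed fewer than the 1731 called in the data, so the shares found in the data may differ.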

Results

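The series measured RNA in primary hippocampal cells dissected from E18 mouse embryos, a mixed culture of young neurons with some glia and other cells. The cells were infected 7 days after seeding with AAV1/2, an adeno-associated virus, and RNA was taken 7 days later. In 3 samples the virus carried a knockdown construct against Diras2, a Ras-family small GTPase of the brain, and in 3 control samples a scrambled sequence. Each sample was read on 1 Affymetrix expression array, and the number of arrays limits the precision of every value here. RNA integrity numbers were 9, 9.3 and 9.2 in the knockdown samples and 9.2, 9 and 8.8 in the controls. Values were log2 RMA expression levels with array medians between 4.03 and 4.11. Pearson correlations across the genes tested were 0.992 to 0.995 between knockdown arrays, 0.988 to 0.994 between control arrays and 0.981 to 0.989 between the groups. The labels call the samples biological replicates without naming separate cultures or litters, so the p-values measure the spread between these samples, part of which may be technical. The design text names 1 question, which genes change when Diras2 is knocked down, and the series holds this single comparison.

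Diras2 itself was lower in every knockdown array. Its level was 6.49 ± 0.59 (SD, n = 3) in the knockdown and 10.03 ± 0.24 in the control, a log2 difference of -3.54 (SE 0.27) or 11.6-fold, with an adjusted p of 0.00063 by limma. The 3 knockdown values were 7.17, 6.23 and 6.08 and the 3 control values 10.17, 10.17 and 9.76. An exact permutation test of this gene alone gave a two-sided p of 0.1, the smallest that 3 against 3 arrays allow. Diras1, its closest relative, also fell, from 7.29 ± 0.14 to 5.94 ± 0.17, a log2 difference of -1.35 (SE 0.12) with an adjusted p of 0.00105. Whether part of the Diras1 signal comes from Diras2 transcript bound to its probes was left open by the test in the closing section.

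Knockdown of Diras2 was accompanied by changes across the transcriptome in both directions. The samples hold no other knockdown construct, so effects of losing Diras2 cannot be told apart from other effects of the construct. Of 22180 genes tested, 924 rose and 807 fell, together 7.80% of the genes. Of those that rose, 181 were at least 2-fold higher and 11 at least 4-fold, and of those that fell, 165 were at least 2-fold lower and 7 at least 4-fold. The changed genes were mostly well expressed, with a median level of 7.56 for those that rose and 7.37 for those that fell against 4.73 for the rest. Their median change was 0.70 on the log2 scale, against a median SD within groups of 0.15. The groups did not overlap at all for 5650 genes, 25.5% of the total, where chance gives 10% for 3 against 3. With the replicate number as a block 1341 genes rose and 1252 fell, of which 914 and 798 were shared with the fit without it. The counts fell to 418 and 330 without knockdown replicate 2, 492 and 368 without knockdown replicate 3, 383 and 306 without control replicate 2 and 402 and 356 with RNA integrity as a covariate, and were 1401 and 1302 with array weights.

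**Figure D1:**
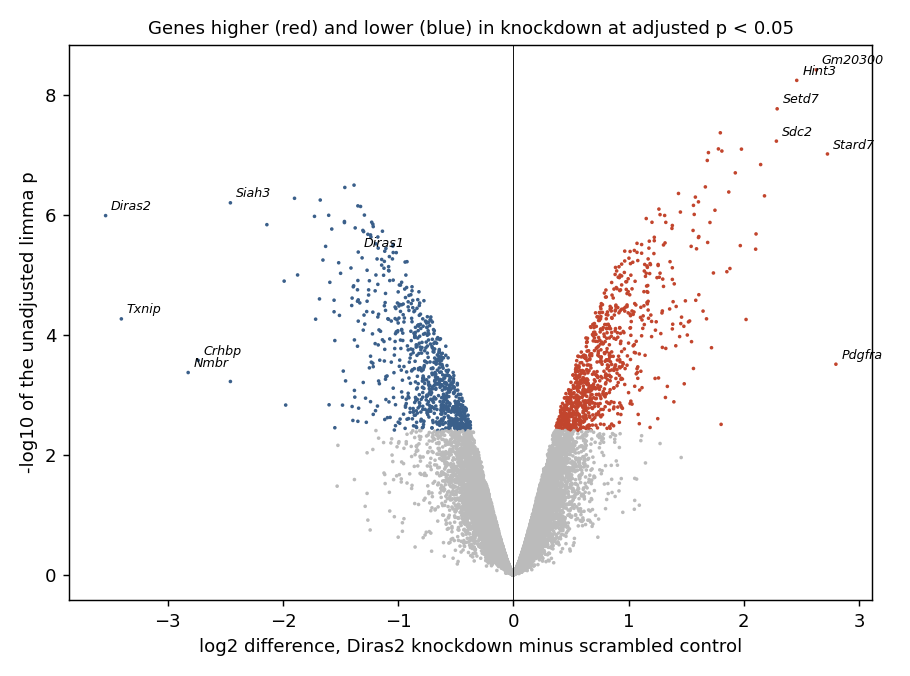
Log2 difference (knockdown minus control, x axis) against -log10 of the unadjusted limma p (y axis) for the 22180 genes tested, each point 1 gene. The 924 genes that rose are red, the 807 that fell are blue and the rest grey; Diras2 is the leftmost point at -3.54.

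Among the largest increases was Pdgfra, the receptor for platelet-derived growth factor found on oligodendrocyte precursors and fibroblasts, which rose from 4.28 ± 0.35, below the median level of genes that did not pass, to 7.08 ± 1.08 (SD, n = 3), a log2 difference of 2.80. Its 3 knockdown values, 5.94, 8.08 and 7.22, were widely spread. Far tighter was the rise of Stard7, a carrier of phosphatidylcholine, by 2.73 (SE 0.16) on the log2 scale. The long non-coding RNA Gm20300 rose by 2.63 (SE 0.10), Hint3, a nucleotide hydrolase, by 2.46 (SE 0.10) and Setd7, a lysine methyltransferase, by 2.29 (SE 0.10). Sdc2, a heparan sulfate proteoglycan of dendritic spines, rose 4.87-fold, and Prkg1, a kinase activated by cyclic GMP, 4.53-fold. Mmgt1, a subunit of the complex that inserts membrane proteins in the endoplasmic reticulum, rose 4.43-fold, and Bcap29, another endoplasmic reticulum membrane protein, 4.31-fold. Grb10, an adaptor that dampens insulin receptor signalling, rose 4.30-fold, Gnal, the olfactory-type stimulatory G protein, 4.06-fold, and Unc80, a subunit of the neuronal sodium leak channel, 3.95-fold. Adjusted p-values by limma ran from 6.31e-05 for Gm20300 and Hint3 to 0.0104 for Pdgfra, whose call was lost without control replicate 2 (0.0575) and with RNA integrity as a covariate (0.0514).

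After Diras2, the gene that fell most was Txnip, the inhibitor of thioredoxin that responds to glucose, from 9.11 ± 0.74 to 5.71 ± 0.77 (SD, n = 3), 10.6-fold. Nmbr, the receptor for neuromedin B, had a log2 difference of -2.82 (SE 0.49) and Crhbp, which binds corticotropin-releasing hormone, -2.74 (SE 0.45). Siah3, of the Siah family of ubiquitin ligases, fell 5.49-fold, and Akr1c18, an enzyme that inactivates progesterone, fell to a low level, from 6.61 ± 1.03 to 4.15 ± 0.36. Dap, a death-associated protein that restrains autophagy, fell 4.41-fold and Slc6a6, the taurine transporter, 3.31-fold. Tac1, the precursor of substance P, had a log2 difference of -1.98 (SE 0.42). AW551984, Mfsd11 and Cabcoco1 fell 3.97-fold, 3.73-fold and 3.66-fold. Adjusted p-values by limma ran from 0.000555 for Mfsd11 to 0.0277 for Tac1. Without control replicate 2 the calls of Crhbp (0.0533), Nmbr (0.0590), Akr1c18 (0.0634) and Tac1 (0.106) were lost, as were those of Nmbr (0.0652), Akr1c18 (0.0630) and Tac1 (0.0663) without knockdown replicate 2, of Akr1c18 (0.0688) and Tac1 (0.0868) without knockdown replicate 3 and of Tac1 (0.0790) without knockdown replicate 1. Those of Crhbp (0.0522) and Tac1 (0.118) were also lost with RNA integrity as a covariate.

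**Figure D2:**
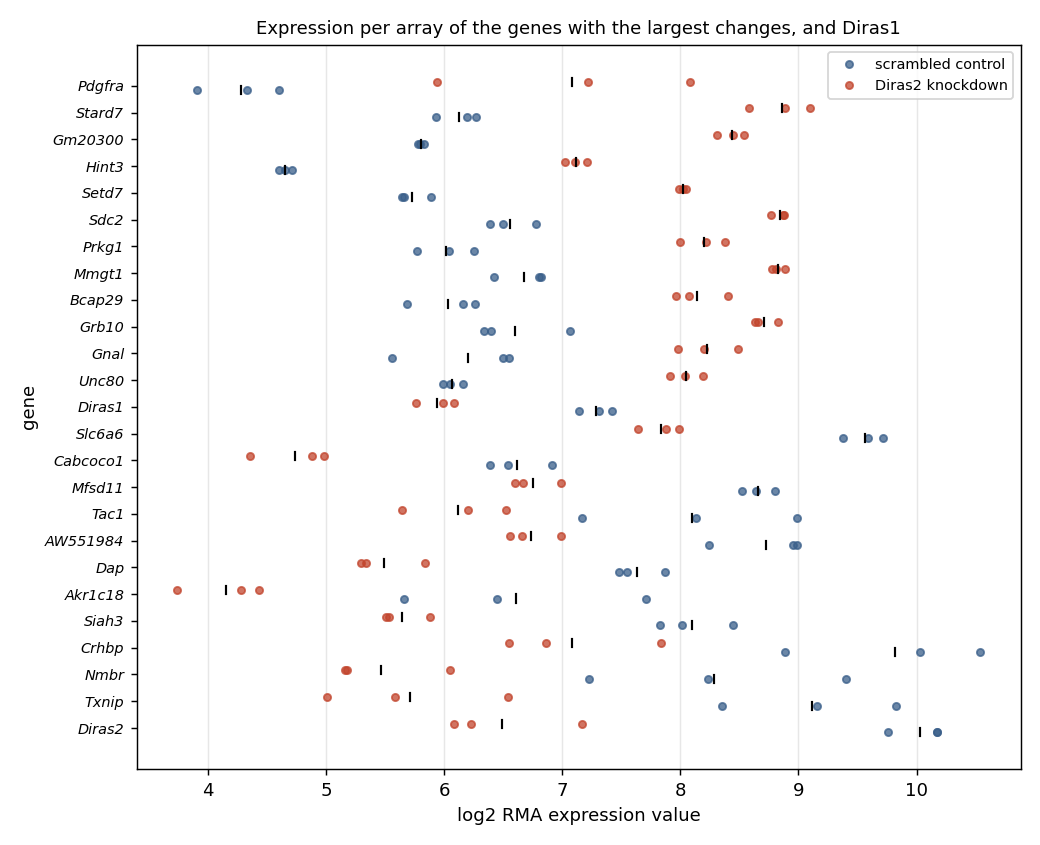
Log2 RMA expression (x axis) of the genes with the largest changes and of Diras1 (y axis), with 1 point per array, knockdown in red and scrambled control in blue, and a black bar at each group mean. The genes other than Diras1 were chosen among those whose 3 knockdown values lie all above or all below the 3 control values. The same holds for Diras1. Diras2 means are 6.49 and 10.03.

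Gene lists fixed before the data were examined were then compared with all other genes. Of 30 lists tested, 3 shifted up and 4 down by camera at its preset correlation of 0.01 between genes. The lists that rose held cell cycle, cholesterol and stress response genes, and those that fell adhesion, lysosomal, immediate-early and inhibitory neuron genes. With the correlation between genes estimated for each list, 0 of the 30 passed, where 2 had an unadjusted p under 0.05, and by fry, which asks only whether a list moved one way, 2 did, adhesion and autophagy. The list calls therefore rest on the preset correlation, and other splits of the 6 arrays gave as many shifted lists or more, as the closing section sets out.

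Of 33 measured cell cycle genes 10 rose, 1 fell and 22 did not pass the test, with a median log2 difference of 0.46, and 28 lay above 0. The list shifted up by camera with an adjusted p of 2.01e-07, and had an adjusted p of 0.750 with an estimated correlation. Adjusted over the list alone, 16 rose and 1 fell. Rrm2, a subunit of the reductase that makes deoxynucleotides, rose 3.01-fold, and Mcm3 and Mcm2, of the replicative helicase, rose by 0.99 (SE 0.16) and 0.61 (SE 0.11) on the log2 scale. Pcna, the sliding clamp of DNA polymerase, went the other way with -0.61 (SE 0.10). Mki67, the proliferation antigen, and Top2a, a topoisomerase of dividing cells, named after their values were seen, rose by 1.48 and 1.32 on the log2 scale from levels of 4.81 ± 0.22 and 4.14 ± 0.05 (SD, n = 3). Rrm2 has a second, dim probe set that showed a log2 difference of -0.10. Markers of astrocytes, microglia, endothelial cells and fibroblasts, pooled, had a median log2 difference of -0.04, and the oligodendrocyte lineage list one of 0.08. Within that lineage 7 precursor markers, Pdgfra among them, had a median of 0.52 (bootstrap 95% interval -0.05 to 0.66). With the replicate block 15 members rose. Higher members numbered 2 without control replicate 2, 3 without knockdown replicate 3, 4 without knockdown replicate 2 and 6 without control replicate 1 or 3; Mki67, Top2a, Mcm2 and Pcna lost their calls without 1 or more of control replicates 2 and 3 and knockdown replicates 2 and 3 (adjusted p from 0.0508 to 0.0963), while Rrm2 and Mcm3 did not, and Mcm2 (0.0796) and Top2a (0.0940) also lost theirs with RNA integrity as a covariate.

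Cholesterol biosynthesis genes had a median log2 difference of 0.45, and 18 of 19 measured members lay above 0. The median ran from 0.28 without control replicate 3 to 0.68 without knockdown replicate 3. Of the 19, 3 rose, 0 fell and 16 did not pass the test, and 4 rose when adjusted over the list alone. Insig1, the sterol-regulated protein that holds back cholesterol synthesis, rose 2.02-fold. Lss, lanosterol synthase, rose 2.35-fold and Msmo1, a sterol oxidase, rose by 0.59 on the log2 scale. Sc5d, a sterol desaturase, had a log2 difference of 0.53 and an adjusted p of 0.0718, and of 0.0159 with the replicate block, under which 11 members of the list rose. As a list they had an adjusted p of 0.000122 by camera and of 0.750 with an estimated correlation. The count was 1 without knockdown replicate 2 or control replicate 2 and 2 without knockdown replicate 1, knockdown replicate 3 or control replicate 3; Lss lost its call without knockdown replicate 2 (0.0710) and control replicate 2 (0.0696), and Msmo1 without every array but control replicate 1 (0.0518 to 0.162). Both also lost theirs with RNA integrity as a covariate (0.0721 and 0.184), and Msmo1 with median centring (0.0517).

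Of 29 measured genes of the unfolded protein and integrated stress responses 5 rose, 0 fell and 24 did not pass the test, 24 lay above 0 and the median log2 difference was 0.15. The list shifted up by camera with an adjusted p of 0.000965, and had an adjusted p of 0.750 with an estimated correlation. Adjusted over the list alone, 6 rose. Some members that did not pass are named after their values were seen. Hspa5, Hsp90b1 and Xbp1 had log2 differences of 0.06, -0.06 and 0.03. Atf4 had 0.62 and an adjusted p by limma of 0.119 (0.0455 with the replicate block). Pdia6, a disulfide isomerase of the endoplasmic reticulum, rose 2.09-fold. Psat1 and Shmt2, enzymes of serine and one-carbon metabolism, each rose 1.67-fold, and Ddit4, an inhibitor of mTORC1, 1.79-fold. The fifth, named after its values were seen, was Asns, asparagine synthetase, at 1.36-fold. The count was 2 without knockdown replicate 2 or control replicate 2 and 3 without knockdown replicate 1, knockdown replicate 3 or control replicate 1. It was 7 without control replicate 3. Asns lost its call without each array in turn (0.0780 to 0.153). Ddit4 lost its call without knockdown replicate 1, knockdown replicate 2 or control replicate 2 (0.0544 to 0.0848). Shmt2 lost its call without knockdown replicate 2, knockdown replicate 3, control replicate 1 or control replicate 2 (0.0533 to 0.0856). All 3 also lost theirs with RNA integrity as a covariate (0.0841 to 0.128), and Asns with quantile normalisation (0.0780) and robust fitting (0.0502).

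Of 41 measured cadherins and synaptic adhesion molecules 11 fell, 1 rose and 29 did not pass the test, 32 lay below 0 and the median log2 difference was -0.20. The list shifted down by camera with an adjusted p of 0.000122, and had an adjusted p of 0.307 with an estimated correlation and of 0.0380 by fry. Adjusted over the list alone, 15 fell and 3 rose. Lrrtm2, a postsynaptic partner of neurexins, fell from 9.98 ± 0.11 to 9.05 ± 0.08 (SD, n = 3), a log2 difference of -0.93. Flrt2, an adhesion and repulsion cue of neurons, fell 2.46-fold, and the classical cadherins Cdh20 and Cdh10 fell 2.32-fold and 1.56-fold. The member that rose, named after its values were seen, was another cadherin, Cdh12, by 0.92 (SE 0.22) on the log2 scale. With the replicate block 14 members fell and 4 rose. Members that fell numbered 3 without control replicate 2, 4 without knockdown replicate 2 and 6 without knockdown replicate 3; the call of Cdh20 was lost without control replicate 2 (0.0574) and that of Cdh12 without every array but knockdown replicate 1 (0.0667 to 0.152), with RNA integrity as a covariate (0.159) and with quantile normalisation (0.0534).

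Of 26 measured autophagy and lysosome genes 7 fell, 1 rose and 18 did not pass the test, with 20 below 0, and 10 fell and 2 rose when adjusted over the list alone. The list shifted down by camera with an adjusted p of 0.000965, and had an adjusted p of 0.327 with an estimated correlation and of 0.0380 by fry. Ulk1, the kinase that starts autophagy, fell 1.73-fold. The lysosomal proteins Ctsb, a protease, Npc2, a cholesterol carrier, and Grn, progranulin, fell 1.69-fold, 1.57-fold and 1.51-fold. Atg5, needed to build autophagosomes and named after its values were seen, was the member that rose, 1.44-fold. With the replicate block 8 members fell and 2 rose. Members that fell numbered 3 without knockdown replicate 2, knockdown replicate 3 or control replicate 2; the call of Grn was then lost (0.0768, 0.0743 and 0.0731), and that of Atg5 without these or control replicate 3 (0.0535 to 0.103). Grn (0.0872), Atg5 (0.109) and Npc2 (0.0505) also lost theirs with RNA integrity as a covariate.

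Immediate-early genes and feedback regulators of MAP kinase signalling had a median log2 difference of -0.37, with 25 of 30 measured members below 0. Singly, 1 fell, 1 rose and 28 did not pass the test, the same numbers when adjusted over the list alone. Dusp4, a phosphatase that inactivates MAP kinases, fell 2.47-fold, and Spred1, an inhibitor of Ras-to-Raf signalling, rose 1.59-fold. Jun, a subunit of the AP-1 transcription factor, had a log2 difference of -0.45 and Spred2, a relative of Spred1, one of -0.41, with adjusted p-values of 0.0855 and 0.0802, and of 0.0299 and 0.0490 with the replicate block, under which 7 members fell. The list had an adjusted p of 0.00618 by camera and of 0.750 with an estimated correlation. Its call was lost without knockdown replicate 1 (0.190, median -0.11) and control replicate 3 (0.0618, median -0.18), the call of Dusp4 without knockdown replicate 2 (0.0679) and control replicate 2 (0.0780) and with RNA integrity as a covariate (0.0801), and 4 members fell without control replicate 1.

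Markers of inhibitory neurons were the list with the lowest median, -0.38, and 15 of 17 measured members lay below 0. Of these 1 fell, 0 rose and 16 did not pass the test, the same numbers when adjusted over the list alone. Lhx6, a transcription factor of interneurons from the medial ganglionic eminence, fell from 8.77 ± 0.27 to 7.57 ± 0.27 (SD, n = 3), 2.30-fold. Maf, Dlx2 and Erbb4, further interneuron genes, had log2 differences of -0.64, -0.60 and -0.52 with adjusted p-values of 0.148, 0.166 and 0.0785, and of 0.0276, 0.0442 and 0.0555 with the replicate block, under which 5 members fell. Gad1, Slc32a1 and Gad2, named after their values were seen, had log2 differences of 0.11, -0.22 and -0.45 and did not pass. Camera gave the list an adjusted p of 0.00618, and 0.750 with an estimated correlation. Its call was lost without control replicate 2 (0.0567), and 5 members fell without control replicate 1, where the median was -0.615. Without knockdown replicate 2 the immediate-early list had a lower median, -0.388 against -0.373.

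**Figure D3:**
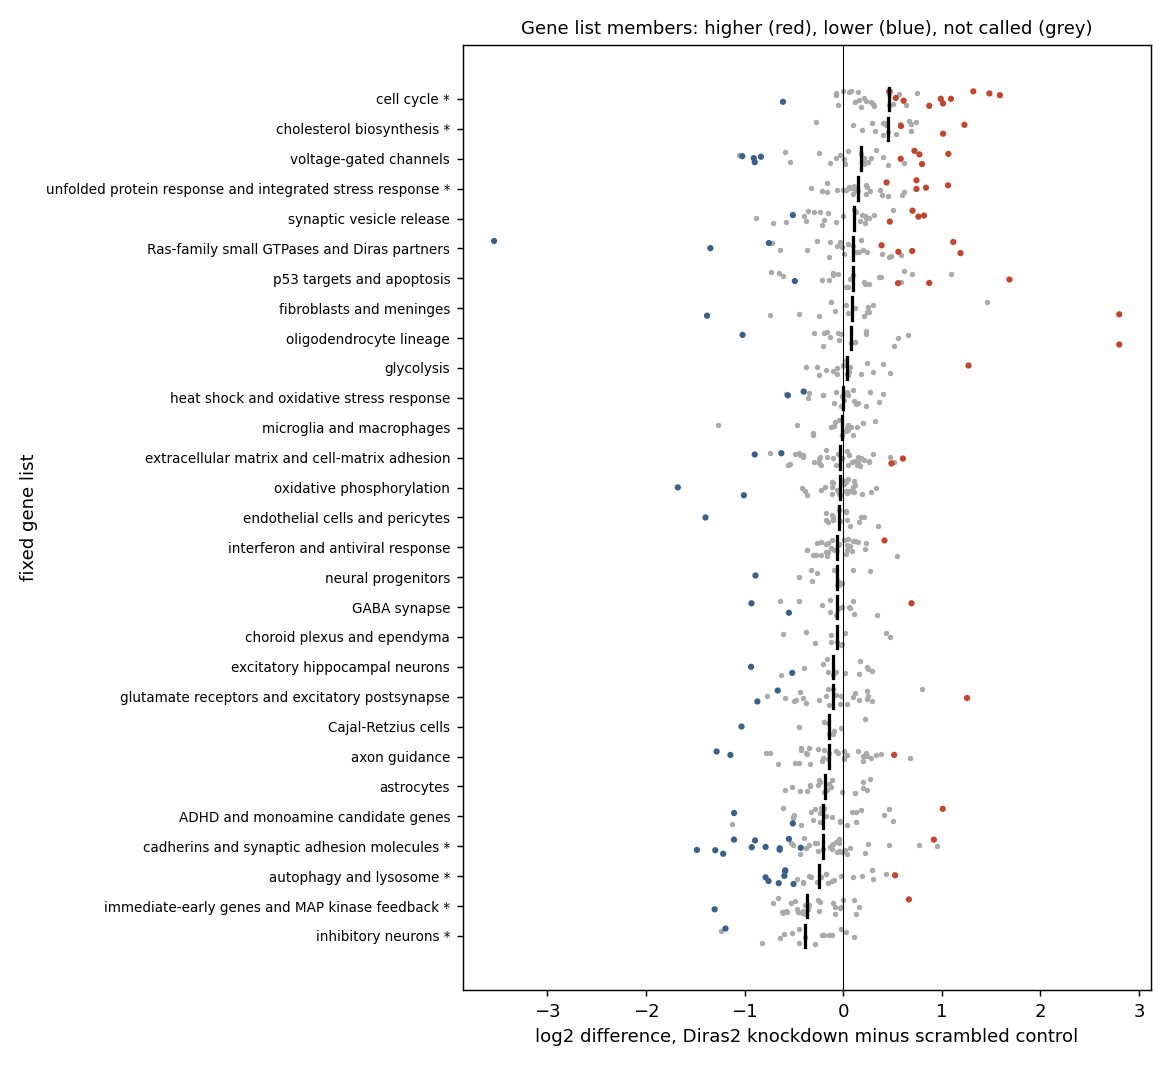
Log2 difference (knockdown minus control, x axis) of each measured member of the gene lists reported here (y axis), red where the gene rose, blue where it fell and grey where it did not pass the test, with a black bar at each list median. Lists with an asterisk passed camera at its preset correlation; medians run from -0.38 for inhibitory neurons to 0.46 for cell cycle genes.

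The list of Ras-family GTPases and their partners, to which Diras2 belongs, did not shift (adjusted p 0.555). Of 29 measured members 5 rose, 3 fell and 21 did not pass the test, and 7 rose and 6 fell when adjusted over the list alone. Besides Diras2 and Diras1, Nras, one of the classical Ras proteins, changed most, rising from 7.15 ± 0.07 to 8.34 ± 0.18 (SD, n = 3), 2.28-fold. Rap2c, of the Rap branch, rose 2.17-fold. The list median was 0.10 and its mean -0.04, while the test pointed up, and 7 members rose and 6 fell with the replicate block. Members that rose numbered 2 without knockdown replicate 2 or control replicate 2, 3 without knockdown replicate 1 and 4 without any 1 of the others, and 3 or 4 fell; Nras and Rap2c kept their calls in each.

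Lists of synaptic and excitability genes held changed genes in both directions and did not pass as lists with all 6 arrays. Camera tests a shift in 1 direction, so opposite changes within a list can cancel. Of 29 synaptic vesicle genes 4 rose and 1 fell (adjusted p 0.641; 4 and 4 over the list alone). Vamp2 rose 1.70-fold, and the calcium sensors Syt4 and Syt7 rose 1.77-fold and 1.63-fold. Rab3c, a vesicle GTPase, rose 1.39-fold, with a log2 difference of 0.16 at its other probe set. Of 29 voltage-gated channel genes 5 rose and 4 fell (adjusted p 0.391, and 7 and 7 over the list alone). The counts were 2 and 0 without knockdown replicate 2 or 3 and 1 and 0 without control replicate 2. They were 6 and 4 without control replicate 1. The potassium channel Kcna1 rose 1.74-fold, the calcium channel Cacna1d 2.09-fold and the sodium channel subunit Scn2b 1.65-fold, and the sodium channel Scn3a fell 1.78-fold. Of 27 glutamate receptor and postsynaptic genes 1 rose and 2 fell (adjusted p 0.290, and 0.0116 without control replicate 3, where the list passed; 1 and 3 over the list alone). Grin2a, a subunit of the NMDA receptor, rose 2.39-fold. Grm5, a metabotropic receptor, fell 1.83-fold and Cacng2, which traffics AMPA receptors, 1.58-fold, the latter with -0.05 at its other probe set, and Shank2, a postsynaptic scaffold, had -0.50 and an adjusted p of 0.0586 (0.0241 with the replicate block). Of 16 GABA synapse genes 1 rose and 2 fell (adjusted p 0.342; 1 and 3 over the list alone): the receptor subunit Gabrg3 rose 1.62-fold, its relative Gabra3 fell 1.90-fold and the adhesion protein Nlgn2 1.46-fold, while Gabrg1 had -0.64 and an adjusted p of 0.0988 (0.0166 with the replicate block). Under the block 4 vesicle, 7 channel and 6 glutamate genes fell. The vesicle and channel genes that rose without the block also rose with it. They were joined by the vesicle gene Cplx2 (adjusted p 0.0287) and the channel genes Cacna1h (0.0220) and Scn8a (0.0488). Leaving out 1 array ended the calls of Rab3c, Grm5, Cacng2, Gabrg3, Gabra3, Nlgn2, Scn2b, Scn3a and Cacna1d for 1 or more of the 6 arrays (adjusted p from 0.0519 to 0.142), most often without control replicate 2, where all 9 lost theirs. RNA integrity as a covariate ended 7 of these, all but Gabra3 and Scn3a (0.0554 to 0.148), the mean over probe sets those of Rab3c (0.148) and Cacng2 (0.0608) and quantile normalisation that of Rab3c (0.0716); those of Vamp2, Syt4, Syt7, Kcna1 and Grin2a held in each of these.

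Lists of axon guidance genes and of candidate genes for attention-deficit/hyperactivity disorder and monoamine signalling did not pass with all 6 arrays either. Of 36 axon guidance genes 1 rose and 2 fell (adjusted p 0.217, and 0.0402 without control replicate 3, where the list passed; 1 and 3 over the list alone). The ephrin receptor Epha3 fell 2.21-fold, the secreted semaphorin Sema3c fell 2.43-fold and the netrin receptor Unc5c rose 1.43-fold, while Sema3a had -0.74 and an adjusted p of 0.0558 (0.0113 with the replicate block). Of 29 candidate genes 1 rose and 2 fell (adjusted p 0.149; 1 and 3 over the list alone). Nos1, the neuronal nitric oxide synthase, rose 2.01-fold, Cdh13, an atypical cadherin, fell 2.15-fold and Snap25, of the vesicle fusion complex, fell 1.42-fold, while Sorcs3 had -0.50 and an adjusted p of 0.0672 (0.0189 with the replicate block). Under the block 2 guidance genes rose and 6 fell, and 3 candidate genes rose and 5 fell. Without control replicate 2 the calls of Sema3c (0.0848), Unc5c (0.139), Cdh13 (0.0640) and Snap25 (0.168) were lost, and all 4 were lost without knockdown replicate 2 (0.0612 to 0.0985). Knockdown replicate 3 ended those of Sema3c, Unc5c and Snap25 (0.0781 to 0.152), knockdown replicate 1 those of Unc5c and Snap25 (0.0811 to 0.121) and control replicate 1 those of Sema3c, Unc5c and Snap25 (0.0539 to 0.110). Cdh13 (0.0615), Sema3c (0.0920) and Snap25 (0.0966) also lost theirs with RNA integrity as a covariate, Unc5c (0.0599) and Snap25 (0.0592) with quantile normalisation and Snap25 (0.0700) with median centring.

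Stress and metabolic lists outside the stress responses above did not pass the test with all 6 arrays. Of 26 p53 target and apoptosis genes 3 rose and 1 fell (adjusted p 0.101; 6 and 1 over the list alone), and the list passed without knockdown replicate 1 (0.0340) or control replicate 3 (0.00553), with array weights (0.0439) and with RNA integrity as a covariate (0.0323). Trp53inp1, a stress-induced partner of p53 that also acts in autophagy, rose 3.22-fold, Ccng1, a p53-induced cyclin, 1.83-fold and the nuclease Aen 1.47-fold, and the pro-apoptotic Bcl2l11 fell 1.40-fold. Of 23 heat shock and oxidative stress genes 0 rose and 2 fell, Bag3 and Dnajb1 (adjusted p 0.522; 0 and 2 over the list alone), with a median of 0 and a mean of -0.04. Hspa1a and Hspb8 had 0.36 and -0.58 with adjusted p-values of 0.117 and 0.119, the latter 0.0403 with the replicate block. Of 32 interferon response genes 1 rose, the RNA sensor Ddx58, by 0.41 (SE 0.10) on the log2 scale (adjusted p of the list 0.522), and 0 passed over the list alone. Mx2, Psmb8 and Irf7 had -0.37, -0.31 and 0.22 and did not pass. Of 20 glycolysis genes 1 rose, Tpi1, triosephosphate isomerase, 2.40-fold (adjusted p of the list 0.522; 1 over the list alone), while Eno2, Slc2a1 and Bnip3 had 0.30, -0.38 and 0.41 and did not pass, the last at 0.0402 with the replicate block. Of 33 oxidative phosphorylation genes 2 fell (adjusted p 0.342; 2 over the list alone), the complex I subunits Ndufv1, 3.20-fold, and Ndufb5, 2.01-fold, while Sdhb, at 0.0352 with the replicate block, and Ndufs8 had -0.42 and 0.33 and did not pass. Of 40 matrix genes 2 rose and 2 fell (adjusted p 0.392; 2 and 6 over the list alone): Itgb1 rose 1.52-fold and Hapln1 1.40-fold, and Tnc fell 1.86-fold and Ncan 1.54-fold. With the block 8 p53 target genes rose and 4 fell, 5 matrix genes fell, and 2 interferon and 2 glycolysis genes rose. The calls of Trp53inp1, Tpi1, Ndufv1 and Ndufb5 held with any 1 array left out. Without control replicate 2 all the others named here as having risen or fallen lost theirs (0.0517 to 0.176), and all of these but Tnc also lost theirs without knockdown replicate 2 (0.0738 to 0.132) and knockdown replicate 3 (0.0744 to 0.153), several also without knockdown replicate 1, control replicate 1 or control replicate 3 (0.0536 to 0.113). All of them but Ccng1 lost theirs with RNA integrity as a covariate (0.0501 to 0.172), Bcl2l11 and Dnajb1 with median centring (0.0531 and 0.0542), Bcl2l11 and Ddx58 with an intensity trend (0.0554 and 0.0694) and Itgb1 with quantile normalisation (0.0623).

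Markers of other cell types in the culture did not pass as lists with all 6 arrays. Astrocyte markers had a median log2 difference of -0.18 with 0 of 20 past the test (adjusted p 0.149), among them Ttyh1, Atp1b2, Gja1 and Apoe with -0.34, -0.52, -0.59 and -0.44. Their median ran from -0.20 without knockdown replicate 1 to -0.085 without knockdown replicate 2. Excitatory neuron markers had a median of -0.10 with 2 of 15 lower (adjusted p 0.149), the calcium-binding Calb1, 1.91-fold, and the transcription factor Fezf2, 1.43-fold, while Wfs1 and Neurod2 had -0.63 and -0.40 and did not pass. This list passed without control replicate 3 (0.00553) or knockdown replicate 1 (0.0374) and with RNA integrity as a covariate (0.0492). Its median was -0.235 without control replicate 3 and -0.028 without control replicate 1. Progenitor markers had a median of -0.06 with 1 of 13 lower, Tnc (adjusted p 0.149), while Hes1, Fabp7 and Sox2 had -0.45, -0.27 and -0.31, and the list passed without control replicate 1 (0.0154). Cajal-Retzius markers had a median of -0.14 with 1 of 9 lower, Ndnf, 2.05-fold (adjusted p 0.312), while Lhx5, Nhlh2 and Lhx1 had 0.22, -0.45 and -0.15. In the oligodendrocyte lineage Pdgfra rose, Ermn fell from a low level of 4.33 ± 0.20 to 3.31 ± 0.11 and 17 of 19 did not pass (adjusted p 0.680), among them Mog and Gpr17 with -0.29 and 0.56. Among 16 fibroblast and meningeal markers, which share Pdgfra, Fbln1 fell 2.60-fold and 14 did not pass (adjusted p 0.680), among them Lum and Ogn with -0.74 and 1.46. Among 18 endothelial and pericyte markers the pericyte gene Rgs5 fell 2.64-fold (adjusted p of the list 0.550), while Ly6c1, Slco1a4 and Pecam1 had 0.21, 0.35 and -0.18. Microglia had 0 of 19 past the test and a median of -0.01 (adjusted p 0.555), with Csf1r, Cx3cr1, Cd68 and Cd53 at -0.46, -0.31, -1.27 and 0.20. Choroid plexus had 0 of 11 and a median of -0.07 (adjusted p 0.522), with Ak7, Rsph1, Dynlrb2 and Folr1 at -0.38, -0.28, 0.43 and 0.47. Adjusted over the list alone the counts were the same except for fibroblasts, where 2 rose and 2 fell. With the replicate block the adjusted p-values of Gja1 (0.0385), Apoe (0.0492), Wfs1 (0.0108), Hes1 (0.0262), Lum (0.0442), Csf1r (0.0339) and Cd68 (0.0179) passed, so that 2 astrocyte, 2 progenitor, 2 microglial and 2 fibroblast markers fell, and 2 oligodendrocyte markers rose. Of the erythroid list 3 members were measured and it was not tested. Without control replicate 2 the calls of Pdgfra (0.0575), Fezf2 (0.150), Fbln1 (0.0649), Ndnf (0.0522) and Tnc (0.0517) were lost; Fbln1 (0.0587 and 0.0858) and Fezf2 (0.114 and 0.0865) also lost theirs without knockdown replicate 1 or 2, and Fezf2 without knockdown replicate 3 (0.142) or control replicate 3 (0.0853). All 5 lost theirs with RNA integrity as a covariate (0.0501 to 0.150).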

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

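Among these tests only the replicate block with an estimated correlation was chosen after the data were seen; groups, gene lists, naming rule, main fit and the other alternatives were fixed before the data were examined. Diras2 kept its call throughout, between -3.88 and -3.33. Genes that rose numbered 1401 with array weights, 402 with RNA integrity as a covariate, 2415 at unadjusted p and 383 to 800 with 1 array left out. Genes that fell numbered 1302, 356, 2222 and 306 to 687 in the same order, 1238 at an adjusted p under 0.1, 533 with all probe sets tested and 1252 with the replicate block. Shifted lists numbered 0 with an estimated correlation, 2 by fry, 0 with the replicate block and an estimated correlation, and 6 to 10 with 1 array left out. Of 7 shifted lists none turned direction. Uncalled lists turned as follows (adjusted p): with RNA integrity as a covariate, matrix (0.929), heat shock (0.959) and microglia (0.929); with array weights, microglia (0.986); without knockdown replicate 1, vesicle release (0.948); without knockdown replicate 2, oligodendrocyte lineage (0.574); without knockdown replicate 3, fibroblasts (0.885); without control replicate 1, fibroblasts (0.861) and oligodendrocyte lineage (0.860); without control replicate 3, microglia (0.716) and vesicle release (0.946). With 1 array left out these ran from 0.481 to 0.946 for fibroblasts, 0.284 to 0.716 for microglia, 0.199 to 0.860 for the oligodendrocyte lineage and 0.447 to 0.948 for vesicle release. The fall in counts with 1 array left out follows in part from fewer arrays; the cause of the other moves was not tested. Of 127 called genes followed through the alternatives, 10 were removed by the stricter filter on dim genes and not tested there. All kept their direction where tested, and of the 117 tested in each 58 kept their call in each. Among the 127, RNA integrity as a covariate ended 56 calls, quantile normalisation 8, median centring 6 and the replicate block 1, Chrm2; calls of named genes and lists that the block added stand with the results, and it changed no other. Leaving out 1 array ended between 24 (control replicate 3) and 66 (control replicate 2). Control replicate 2 had the highest array weight, 2.42. Of the 689 genes called without it, 681 were also called with all arrays, each in the same direction. Signal over background limits dim genes: uncalled genes had a median level of 4.73.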

Other observations

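The extra gene groups below, the cell cycle tests and the comparison of adhesion with vesicle genes were chosen after the results were seen, and no test of the extra groups as a whole is given for that reason. Of 22 measured genes of the protocadherin beta cluster, which encode neuronal adhesion proteins, 8 rose, 1 fell and 13 did not pass the test, and with the replicate block 13 rose and 1 fell. Their median log2 difference was 0.63, and 20 lay above 0. Pcdhb6 rose 2.30-fold and Pcdhb11 2.09-fold, and Pcdhb16 had -0.64 (SE 0.10). The genes are related in sequence, and whether transcripts of one bind probes of another was not tested. In the small RNA silencing machinery 3 of 19 genes rose and 1 fell, and 3 rose and 2 fell with the replicate block. Ago2, the slicing Argonaute, rose 3.66-fold, from 8.23 ± 0.17 to 10.10 ± 0.16 (SD, n = 3), Dcp2, the decapping enzyme, 2.82-fold and Ago3 1.78-fold, while Cnot7, a deadenylase, fell 1.34-fold, a call lost without any 1 of the 6 arrays (0.0577 to 0.163), with RNA integrity as a covariate (0.147) and with median centring (0.0818).

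Neuropeptides and their receptors had a median log2 difference of -0.26 over 44 measured genes, of which 3 fell, Crhbp, Nmbr and Tac1, and 1 rose, Calcrl, 2.60-fold. With the replicate block 13 fell and 4 rose. The group shares 4 genes, Sst, Npy, Vip and Cck, with the inhibitory neuron list, whose own median was -0.38. The other 40 had a median of -0.22, with 3 lower, and 11 lower with the replicate block. Whether fewer interneurons account for this was not tested. Among 21 acetylcholine receptor genes 4 fell and 0 rose, with a median of -0.06, and with the replicate block 4 fell and 2 rose. The nicotinic subunit Chrna7 fell 3.15-fold, from 9.73 ± 0.07 to 8.07 ± 0.32 (SD, n = 3), Chrnb2 1.64-fold, and the muscarinic receptors Chrm5 and Chrm2 3.03-fold and 1.98-fold. Without control replicate 2 the calls of Crhbp (0.0533), Nmbr (0.0590), Tac1 (0.106), Chrm5 (0.116), Chrm2 (0.111) and Chrnb2 (0.0543) were lost, and each of these but Crhbp also without 1 or more other arrays. RNA integrity as a covariate ended those of Crhbp (0.0522), Tac1 (0.118), Chrm2 (0.134) and Chrnb2 (0.114). With the replicate block Chrm2 had an adjusted p of 0.0526. Among probe sets with no gene named here, 106 rose and 75 fell when all probe sets were tested.

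The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1731 genes and the highest of the others 0 by limma, where those others had 365 to 1618 genes at an unadjusted p under 0.05. Each other split puts knockdown and control arrays together in both groups. Any difference between the treatments then widens the spread within groups and lowers the calls. The 0 therefore does not show how many genes would be called with no treatment difference. For gene lists, the real split shifted 7, the highest other split 16, and 4 of the 10 splits shifted 7 or more. The 3 splits with more lists than the real one each parted 1 of the 3 replicate pairs, and the other 3 splits that part all pairs shifted 6, 0 and 6 lists.

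Of 33 cell cycle genes 10 rose, and the list lost its call with an estimated correlation (adjusted p 0.750). The median over 73 markers of astrocytes, microglia, endothelial cells and fibroblasts was -0.04 (bootstrap 95% interval -0.11 to 0.03), below the cell cycle median of 0.46 (0.21 to 0.53). Of the 73, 37 lay at or below the median level of all genes, where a rise could be hidden, and the 36 above it had a median of -0.08 (-0.28 to 0.12), also below the cell cycle median. Within these arrays this argues against a lower share of neurons with every other cell type raised alike. The intervals hold the spread between genes and not between samples. More oligodendrocyte precursors could account for the cell cycle rise. Their 7 markers had a median of 0.52, but the interval from -0.05 to 0.66 leaves this open. Pdgfra alone among them was called. Lhfpl3, Gpr17, Olig2 and Sox10 had 0.66, 0.56, 0.52 and 0.23, and Olig1 and Cspg4 had -0.19 and -0.05. More division in another single cell type, as a response to the knockdown, was not tested.

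Adhesion genes, of which 11 of 41 fell, span a median of 177 kb against 16.3 kb for all genes, so a general fall of long genes was weighed. Among genes above the median expression, only the decile of longest span had a negative median, -0.07, with 73 genes higher and 113 lower. Of 10000 random lists matched on span and expression, 36 had a median as low as -0.20. Their middle 95% ran from -0.16 to 0.10, which argues against a general fall of long genes as the whole cause. These draws take genes as independent, so their spread may be too narrow. By camera with an estimated correlation the adhesion list had an adjusted p of 0.307. A lower share of neurons was weighed through vesicle release genes, whose median of 0.11 had an interval from -0.22 to 0.22 that includes the adhesion median, so it stays open. A response of neurons to the knockdown is a further hypothesis, which may hold beside these and was not tested.

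The lower Diras1 signal may come from Diras2 transcript that binds Diras1 probes, from a knockdown construct that also targets Diras1, or from lower Diras1 expression. Between arrays of one group the Diras1 and Diras2 deviations correlated at -0.89 over the 6 arrays, where such binding predicts a positive value. A one-sided exact permutation test gave a p of 0.0556 among 36 permutations. That is the smallest p these values allow, because Diras2 has tied control values of 10.17, so the test could not decide. The explanations therefore stay open. The permutations also set aside the pairing of replicates, and the construct's sequence was not analysed here.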
